A study of Streptomyces rapamycinicus and Streptomyces griseus with 12 samples.

How the data were processed

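Total RNA of 12 libraries was sequenced by the authors from libraries made with Illumina protocols, with 3 libraries for each of 4 groups: *S. griseus* and *S. rapamycinicus*, each with and without the PQQ operon. Groups were taken from the labels. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie2 and DESeq2 1.20.0. The read counter, the genome builds and the annotations are not given in the sources used here.

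The 2 tables used here are the authors' deposited results of one comparison per species. Per the file headers, each row holds a mean normalized count over all libraries, which was treated as a signal with no error of its own. The log2 fold change and its standard error in the authors' deposited tables are on the log2 scale. The Wald statistic is a score in the deposited tables, and the deposited p-value and adjusted p-value go with it. The statistic equalled the fold change over its standard error in the deposited tables, and Benjamini-Hochberg adjustment of the p-values that were listed with an adjusted value gave the deposited adjusted values within 1e-06. Fold changes, SEs and adjusted p-values of single genes in the text are therefore the authors' own, from DESeq2 per the submitters' processing notes. They carry no SD or n of their own.

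Values per library were not used here, because the tables hold none. Replicates could thus not be compared, and the depth of each library, the share of reads in ribosomal RNA and any batch are unknown. The sign of a fold change has no named numerator, and it was not inferred from the values. The counts per group quoted as estimates come from the mean count and the fold change with equal group sizes.

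There were 5057 genes for *S. griseus*, 677 with a symbol, and 10178 for *S. rapamycinicus*, 831 with a symbol. No p-value was listed for 242 and 97 rows, and a further 99 and 394 rows had a p-value but no adjusted one, the latter kind with mean counts up to 1.547 and 2.689. Both kinds were left out of all counts of changed genes. A gene was called changed at an adjusted p below 0.05. The precision followed the mean count: the median SE in *S. griseus* was 3.11 below 10 normalized counts and 0.27 at 1000 or more, and in *S. rapamycinicus* 1.63 and 0.23.

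The quasi-likelihood test of edgeR, set tests on log2 values of each library and biosynthetic clusters built from product names had been planned but could not be run, because the deposited tables hold no counts per library and no products. Instead, the deposited statistics were used in place of the first and the sets were tested with cameraPR of limma 3.58.1 in R 4.3.3. It was run on the deposited Wald statistic with a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over lists of at least 5 members (25 lists in *S. griseus*, 31 in *S. rapamycinicus*). A correlation cannot be estimated without values per library, so it was not checked which calls would hold with an estimated correlation. The deposited Wald statistics of neighbouring tags had a Spearman's rho of 0.316 in *S. griseus* and 0.536 in *S. rapamycinicus*. The adjusted p-values of lists with neighbouring members may therefore be too small. The background was the genes with a symbol and a p-value, since only these could belong to a list. That background was made the main one after results with both backgrounds had been seen; against all genes with a p-value, 8 and 10 lists passed in place of 7 and 4. The polyketide, non-ribosomal peptide, streptomycin, quinoprotein and pathway regulator lists need product names or older tags and were not analysed here.

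Gene lists were matched by symbol. The patterns of 24 lists were planned and then written as symbols once the symbols in the tables were known, and 14 lists were added after that. Both were written before the members' values were examined, except that values of *pqq*, *paaC*, *rapZ*, *aac(3)*, *mraY*, *glmU*, *ssrA* and *rnpB* rows had been seen. The genes named in the text followed a rule: all genes of the PQQ list; the 8 highest and 8 lowest changed genes with a symbol, and 2 without, at an absolute log2 fold change of at least 1 and a mean count of at least 143.8 in *S. griseus* and 138.1 in *S. rapamycinicus*, a fixed share of the summed mean counts; and up to 2 changed members of each list. Not every gene that met the rule is printed, and one of them is not reported here. The planned rule used depth-scaled counts and separation of the libraries; the share of the summed mean counts replaced the former, and the latter could not be checked. Fitted folds beyond 15 on the log2 scale, which arise when one group is close to 0 counts, were given no size.

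Runs were consecutive tags (numbers 5 apart) with calls of one sign. They were compared with 1000 shuffles of blocks of 5 tags and, in *S. griseus*, of single tags as well. The species were compared over symbols found once in each table, by the difference of log2 fold changes over the combined SE with a normal distribution, and permutation tests of correlations used 100000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

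The calculations were tested on simulated data with 200 changed genes, 1 shifted list and 1 changed run of 20 tags, with the deposited SEs of genes with a mean count of at least 50. Simulated for *S. griseus* over 3170 genes, 42.6% of genes with a log2 fold of 1 and 67.6% of those with 2 were called, and 6.4% of the calls were unchanged genes. For *S. rapamycinicus* over 5586 genes these values were 41.3%, 94.4% and 4.0%. A shifted list was called in each simulation, with 0 of 20 and 0 of 27 other lists. The simulated errors were independent between genes, unlike the correlated statistics of neighbouring tags. The simulations therefore cannot show how many calls would be false under such correlation. The planted run was located from the planted genes and not from calls, so it tested only the counting of runs.

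One alternative, a mean count of at least 50, was planned. The others were chosen after seeing the data: adjustment over every gene with a p-value, scaling to the summed counts with or without the 10 most abundant genes, centring on the median of all genes or of 10 equal spans of tag numbers, leaving out fitted folds beyond 15, ranks in place of the Wald statistic, and another background for the lists. The summed counts were approximated from mean counts and fold changes.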

Results

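The study sequenced total RNA from 2 soil actinomycetes, *Streptomyces griseus* and *S. rapamycinicus*, each grown with and without the gene operon for pyrroloquinoline quinone (PQQ), a redox cofactor of bacterial dehydrogenases. The stated question was how the operon affects the expression of biosynthetic gene clusters, the neighbouring genes that together make a natural product. There were 4 groups of 3 libraries, 12 libraries in all. No label said whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The values came as the authors' deposited table of one comparison per species, with an average normalized count, a log2 fold change, its standard error (SE) and p-values for each gene. Total counts per library were not part of these tables, so the depth of each sample is unknown here. The 10 most abundant genes held 69.2% of the summed average counts in the authors' deposited table of *S. griseus* and 72% in that of *S. rapamycinicus*.

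The tables did not name the group in the numerator of the fold change. A positive log2 fold change below means a higher level in that unnamed group, and a negative one a lower level. The numerator may also differ between the species, so neither sign is given as an effect of the operon. Genes with a symbol are named by it, since no product names, coordinates or genome build were used here.

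Transcripts of the PQQ biosynthesis genes differed between the *S. rapamycinicus* groups, and all 5 genes with a *pqq* symbol were positive. In the authors' deposited table, the log2 fold change was 1.02 (SE 0.35, adjusted p = 0.0129) for *pqqA*, which encodes the precursor peptide, and 1.71 (SE 0.35) for *pqqB*. The authors' deposited table gave 2.32 (SE 0.27) for *pqqC*, the oxidase of the last step, and 2.69 (SE 0.57) for *pqqE*, the radical SAM enzyme that joins the precursor's side chains. For *pqqD* the authors' deposited table listed 3.79 (SE 1.53, adjusted p = 0.0431) at an average of only 5.7 normalized counts. Transcripts of *pqqA*, which had the smallest fold change of the 5, were not restricted to one group. The deposited values place it at an estimated mean of 424.5 normalized counts in the numerator group and 208.8 in the other. Adjusted over the list alone all 5 genes passed too, which follows from their calls over all genes and adds no support. As a set they did not stand out from the other genes with a symbol (limma cameraPR, Benjamini-Hochberg adjusted p = 0.154), though they did against all genes (adjusted p = 0.0161), with ranks (adjusted p = 0.0397) and when centred on spans of tag numbers (adjusted p = 0.0201). With fold changes scaled to the summed counts, *pqqA* had 0.72 (adjusted p = 0.102) and *pqqD* 3.48 (adjusted p = 0.067). Centred on the median of all genes, *pqqD* had 3.65 (adjusted p = 0.0534). The authors' deposited table of *S. griseus* was searched for the same symbols and held 0 of them.

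**Figure D1:**
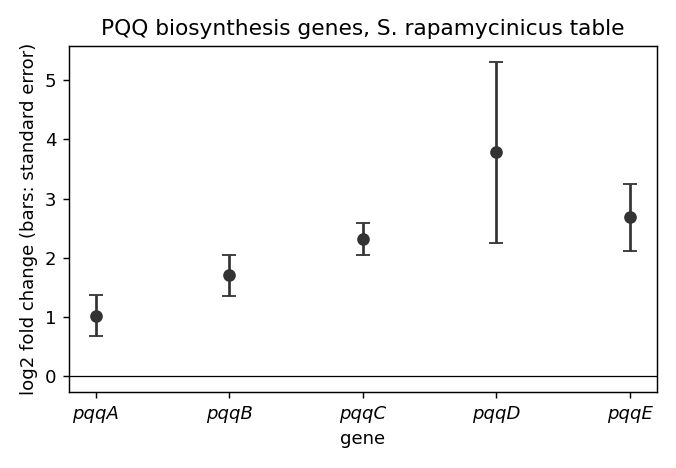
Log2 fold changes of the 5 PQQ biosynthesis genes in the authors' deposited table of *S. rapamycinicus* (points, with bars of 1 standard error, on the vertical axis; genes on the horizontal axis). All 5 points lie above 0, from 1.02 for *pqqA* to 3.79 for *pqqD*, whose average count was the lowest.

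The genes with a symbol named next had the largest positive fold changes in *S. rapamycinicus* above the count limit of the naming rule, and no shared function was tested for them. In the authors' deposited table, *rfbB* (LIV37_RS06635) had a log2 fold change of 7.71 (SE 0.49) and its neighbour *rfbA* (LIV37_RS06640) 6.77 (SE 0.51); both act in the synthesis of dTDP-sugars. The authors' deposited table listed 6.57 (SE 0.73) for *vioC* and 5.07 (SE 0.52) for *vioD*, symbols used for enzymes of viomycin biosynthesis. A log2 fold change of 6.45 (SE 0.26) stood in the authors' deposited table for *gabT*, an aminobutyrate transaminase, and 4.94 (SE 0.49) for the glycerol kinase gene *glpK*. For *ccrA* (LIV37_RS13380), encoding a crotonyl-CoA carboxylase that supplies extender units to polyketide synthases, the authors' deposited table gave 4.70 (SE 0.38). Among genes without a symbol, LIV37_RS06605 (10.42, SE 0.87) and LIV37_RS31485 (9.65, SE 1.27) had the highest values in the authors' deposited table by the rule for named genes. Their estimated means in the lower group were 0.9 and 1.2 normalized counts, so the size of these folds is poorly bounded.

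Negative fold changes reached a similar size. The authors' deposited table listed −6.96 (SE 0.31) for *menE* and −5.77 (SE 0.71) for *menC*, named for menaquinone synthesis. It was −6.70 (SE 0.88) in the authors' deposited table for *hppD* at LIV37_RS28025, a hydroxyphenylpyruvate dioxygenase of tyrosine breakdown. A second *hppD* row, LIV37_RS30560, was positive at 3.95 (SE 0.21) in the authors' deposited table. For *fabG* (LIV37_RS27995), *hemA* and the isopropylmalate synthase gene *leuA*, the authors' deposited table gave −6.14 (SE 0.67), −5.68 (SE 0.47) and −5.15 (SE 0.31). The authors' deposited table placed the xylose isomerase gene *xylA* at −4.34 (SE 0.22), the glyceraldehyde phosphate dehydrogenase gene *gap* (LIV37_RS48740) at −4.15 (SE 0.40) and *cysC* at −3.55 (SE 0.27). Of the genes without a symbol, LIV37_RS27950 (−12.18, SE 0.55) and LIV37_RS27970 (−10.22, SE 0.57) were lowest in the authors' deposited table, with estimated means of 0.8 and 2.1 normalized counts in the lower group.

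In total, 3040 of 9687 tested *S. rapamycinicus* genes (31.4%) had an adjusted p below 0.05 in the authors' deposited table, 1653 positive and 1387 negative. Of these, 2409 also had an absolute log2 fold change of at least 1, 1316 positive and 1093 negative. This split depended on scaling: scaled to the summed counts, a shift of 0.31 on the log2 scale, 1124 genes were positive and 1950 negative. Scaled without the 10 most abundant genes, it moved the other way, to 1770 positive and 1312 negative. Centred on the median of all genes, 1399 were positive and 1627 negative.

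Some of the changed genes of *S. rapamycinicus* stood in long stretches of consecutive locus tags that shared a sign. There were 103 runs of 5 or more, which held 771 genes, or 25.4% of those changed. Of these runs, 19 had 10 or more genes, 8 positive and 11 negative, and they held 262 genes. The longest run had 22 genes, *vioC* and *vioD* among them, with a median log2 fold change of 4.50 over the authors' deposited table. A run of 20 genes with *rfbA*, *rfbB* and a *ccrA* had a median of 7.29 in the authors' deposited table, and another 20 genes with *sbnA* and *sbnB* had 3.31. On the negative side, a run of 14 genes around *hemA* had a median of −4.09 in the authors' deposited table, 11 genes with *cysC* and *cysD* had −3.78 and 11 genes around *gap* had −3.61. A run of 14 with 7 *nuo* genes, which encode the proton-pumping NADH dehydrogenase, had −1.74 in the authors' deposited table. The symbols in runs were read after the runs were found. After shuffling blocks of 5 tags 1000 times, runs of 10 or more held at most 66 genes (permutation test, p = 0.001, the smallest these shuffles can give). In the runs of 10 or more the median SE was 0.378, against 0.353 in the other changed genes (permutation test, p = 0.14). The median absolute Wald statistic was 7.99 in them and 3.69 in the others. Locus tags usually follow gene order, but no coordinates were used here and none of these runs was matched to a named product.

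**Figure D2:**
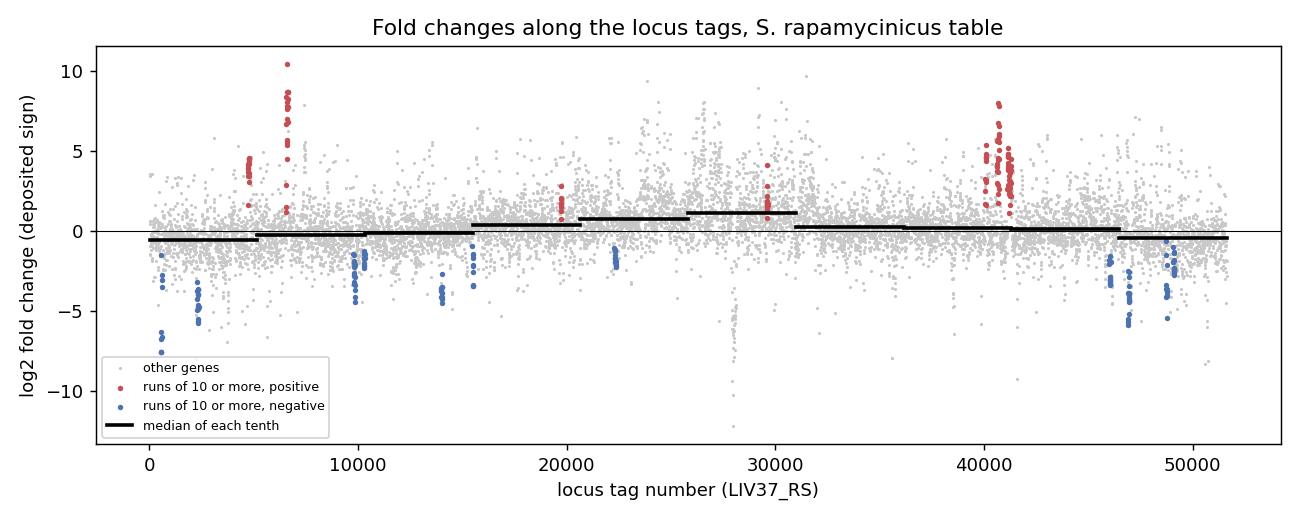
Log2 fold change of each gene in the authors' deposited table of *S. rapamycinicus* (vertical axis) by locus tag number (horizontal axis), without fold changes beyond 15. Coloured points are the 19 runs of 10 or more neighbouring tags with one sign and black bars are medians of 10 equal spans of tag numbers. Those medians went from −0.54 in the first span to 1.11 in the sixth and −0.44 in the last.

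The general level of the fold changes also followed the tag order in *S. rapamycinicus*. Over 10 equal spans of tag numbers, the median log2 fold change of the authors' deposited table was −0.54 in the first span, 1.11 in the sixth and −0.44 in the last. The range of these medians was 1.66, against at most 0.84 after 1000 shuffles of blocks of 50 genes (permutation test, p = 0.001, the smallest possible). Positive calls made up 40.5% of the sixth span and 5.0% of the first. With each gene centred on the median of its span, 2694 genes passed, 1078 positive and 1616 negative.

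Of 52 ribosomal protein genes in the *S. rapamycinicus* table, 27 were positive, 1 was negative and 24 did not pass (cameraPR against the other genes with a symbol, adjusted p = 0.0247); adjusted over the list alone, 31 passed. The authors' deposited table gave log2 fold changes of 2.55 (SE 0.23) for *rplJ* and 2.27 (SE 0.26) for *rplL*, the stalk proteins. This list lost its call when scaled to the summed counts (adjusted p = 0.0626) and when centred on tag spans (adjusted p = 0.602). Of 12 chaperone and heat shock genes, 6 were negative and none was positive among those past the threshold (cameraPR adjusted p = 0.0247), also 6 when adjusted over the list alone. The authors' deposited table gave −1.92 (SE 0.19) for *groES* and −1.72 (SE 0.18) for *groL* (LIV37_RS28215), the chaperonin subunits.

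All 4 ATP synthase genes were negative in *S. rapamycinicus*, too few for a set test, and the authors' deposited table gave −2.16 (SE 0.21) for *atpE* and −1.93 (SE 0.12) for *atpD*. In the respiratory chain list, 7 of 17 genes were negative, 3 were positive and 7 did not pass, and 11 passed when adjusted over the list alone. The authors' deposited table listed −1.92 (SE 0.27) for *nuoH* and −1.76 (SE 0.22) for *nuoE*. The set test of this list gave an adjusted p of 0.168, and 0.0146 when centred on tag spans. Of 8 genes of the tricarboxylic acid (TCA) cycle, 5 were positive (adjusted p = 0.168, and 0.0207 against all genes; 5 adjusted over the list alone), and in the authors' deposited table *sucC* had 1.18 (SE 0.18) and *sucB* 1.17 (SE 0.20). With *sucC* centred on its tag span its value was 0.07 and no longer past the threshold, and the TCA list then had an adjusted p of 0.812.

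The list of acyl-CoA precursor genes had 5 positive members of 8 (adjusted p = 0.0908, 0.00393 against all genes and 0.0138 when centred on tag spans), and 7 adjusted over the list alone. Besides the *ccrA* named above, another *ccrA* (LIV37_RS40070) had 2.51 (SE 0.41) in the authors' deposited table. Of 7 fatty acid synthesis genes, 2 were positive and 2 negative (adjusted p = 0.872; 4 adjusted over the list alone), among them *fabG* at LIV37_RS37760 with 1.85 (SE 0.20) in the authors' deposited table. In glycolysis and the pentose phosphate pathway, 6 of 19 genes were positive and 3 negative (adjusted p = 0.506; 11 adjusted over the list alone), and *fbaA*, the aldolase, had −1.30 (SE 0.16) in the authors' deposited table. In the oxidative stress list, 2 of 16 genes were positive and 5 negative (adjusted p = 0.242; 9 adjusted over the list alone). The authors' deposited table gave −1.54 (SE 0.19) for the catalase-peroxidase gene *katG* (LIV37_RS08960).

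In the authors' deposited table *bldD*, a repressor of sporulation genes, had −1.42 (SE 0.22), while *whiG*, a sporulation sigma factor, had 2.27 (SE 0.83) at 12.6 normalized counts. The *whiG* call was lost when scaled to the summed counts (1.96, adjusted p = 0.057) and when centred on tag spans (1.87, adjusted p = 0.0787). The development list had 1 positive and 2 negative members of 5 (adjusted p = 0.248; 4 adjusted over the list alone) and the sigma factor list 1 and 2 of 6 (adjusted p = 0.838; 4 alone). Nitrite reductase genes were negative, at −1.83 (SE 0.27) for *nirB* and −1.38 (SE 0.26) for *nirD* in the authors' deposited table, in a nitrogen list with 3 negative members of 7 (adjusted p = 0.222; 3 alone). The phosphate list had 0 of 7 members past the threshold (adjusted p = 0.953; 0 alone), though its median was 1.04. Its *pstS* and *pstC* had 1.04 (SE 1.23) and 1.16 (SE 1.09), against SEs of 0.33 and 0.34 in *S. griseus*. These values are too imprecise to show that the 2 genes did not change. Translation factors had 4 positive members of 11 (adjusted p = 0.370; 4 alone), with *tsf* at 1.39 (SE 0.17) and *fusA* at 1.35 (SE 0.19) in the authors' deposited table.

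Few *S. rapamycinicus* genes of natural product classes carried a symbol. Of 5 hopanoid genes in the terpene list, 1 was negative (adjusted p = 0.346; 1 adjusted over the list alone), *hpnH* with −1.12 (SE 0.25) in the authors' deposited table. The list of ribosomally made peptides had 1 positive and 2 negative members of 8 (adjusted p = 0.341; 3 alone), among them *tgmA* with −2.31 (SE 0.39) in the authors' deposited table. Of 3 ectoine genes, 1 was negative, *thpD* with −0.88 (SE 0.22) in the authors' deposited table (1 alone). Both *ltrA* rows of the 5 mobile element rows were negative (2 alone), at −0.68 (SE 0.27) and −0.67 (SE 0.27) in the authors' deposited table, calls that were lost when centred on tag spans and when scaled without the 10 most abundant genes (adjusted p = 0.0564 and 0.0685). None of 6 5S ribosomal RNA rows (adjusted p = 0.506), 3 gas vesicle rows or the 1 aminoglycoside acetyltransferase row *aac(3)* passed, the last with 1.78 (SE 1.12) in the authors' deposited table.

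In *S. griseus*, *treS* and *glgP* had the highest fold changes among genes with a symbol above the count limit of the naming rule and without fitted folds beyond 15. Rarer transcripts had larger values with wider errors. Of the 10 genes in the trehalose and glycogen list 6 did not pass, and its set call was lost with ranks (adjusted p = 0.17). The authors' deposited table gave a log2 fold change of 4.03 (SE 0.32), or 16.3-fold, for *treS*, a trehalose synthase, and 2.52 (SE 0.33) for *glgP*, a glycogen phosphorylase. The branching enzyme gene *glgB* had 2.05 (SE 0.32) in the authors' deposited table. Next to *treS*, SGR_RS10310, which carries no symbol, was 15.9-fold higher in the authors' deposited table, and these 4 genes belong to one run of 5 positive tags. *S. griseus* had 8 runs of 5 and no longer one, against at most 1 after shuffling single tags (permutation test, p = 0.001). Shuffled blocks of 5 tags also gave a median longest run of 5 (permutation test, p = 0.861), but such blocks can keep a run of 5 whole. Another gene without a symbol, SGR_RS05635, had 3.73 (SE 0.42) in the authors' deposited table, and *eboE* had 2.01 (SE 0.42).

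On the negative side, SGR_RS34280 (−7.33, SE 0.36) and SGR_RS34290 (−6.10, SE 0.33), both without a symbol, were lowest in the authors' deposited table by the same rule. Among genes with a symbol above the same count limit and without fitted folds beyond 15, negative values were smaller: the authors' deposited table listed −1.97 (SE 0.66) for *iolB*, of inositol breakdown, and −1.73 (SE 0.27) for the quinolinate synthase gene *nadA*. It was −1.29 (SE 0.30) for *nrdR*, a repressor of ribonucleotide reductase genes, −1.06 (SE 0.25) for *moaA* and −1.02 (SE 0.30) for *uraH* in the authors' deposited table. Centred on tag spans, *iolB* had −1.70 (adjusted p = 0.066).

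In total, 661 of 4716 tested *S. griseus* genes (14.0%) had an adjusted p below 0.05 in the authors' deposited table, 427 positive and 234 negative, of which 501 had an absolute log2 fold change of at least 1 (315 positive, 186 negative). With fold changes scaled to the summed counts without the 10 most abundant genes, a shift of 0.16 on the log2 scale, 338 were positive and 300 negative. Scaled to all summed counts, 409 were positive and 236 negative. Centred on the median of all genes, 508 were positive and 197 negative. Genes that carry a symbol had 109 positive and 25 negative calls among 661 tested.

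Most chaperone genes were positive in *S. griseus*. Of 8, 6 passed and all of these were positive (cameraPR adjusted p = 7.88e-06; 7 adjusted over the list alone), and the authors' deposited table gave 2.43 (SE 0.28) for *groL* (SGR_RS15960) and 1.95 (SE 0.28) for *grpE*. Phosphate uptake genes had 5 positive members of 6 (adjusted p = 0.00247; 5 alone), with 1.98 (SE 0.33) for *pstS* and 1.94 (SE 0.34) for *pstC*, parts of the phosphate transporter, in the authors' deposited table. Of 5 nitrogen genes, 3 were positive (adjusted p = 0.00186; 3 alone), with 2.17 (SE 0.23) for the glutamine synthetase gene *glnA* and 1.55 (SE 0.27) for *ureG* in the authors' deposited table.

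The set tests of central carbon metabolism and ribosomal proteins in *S. griseus* were on the positive side, though many members did not pass. In glycolysis and the pentose phosphate pathway 9 of 16 genes were positive and none was negative among those past the threshold (adjusted p = 0.00563; 10 alone), with 1.42 (SE 0.21) for *pyk* and 0.98 (SE 0.16) for *tpiA* in the authors' deposited table. Another *pyk* row, SGR_RS10385, had 0.58 (SE 0.26) in the authors' deposited table and did not pass. In the TCA cycle 3 of 6 were positive (adjusted p = 0.0451; 4 alone), with 1.21 (SE 0.28) for *sdhA* and 1.16 (SE 0.22) for *sucB* in the authors' deposited table; the adjusted p was 0.0528 among genes with a mean count of at least 50. Of 52 ribosomal protein genes, 13 were positive, 1 was negative and 38 did not pass (adjusted p = 0.019; 16 alone). The authors' deposited table gave 2.18 (SE 0.28) for *rplJ* and 2.18 (SE 0.31) for *rplL*. All 4 fatty acid synthesis genes were positive (4 alone), with 1.93 (SE 0.31) for *fabG* and 1.79 (SE 0.22) for *fabF* in the authors' deposited table, too few for a set test.

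In the ATP synthase list of *S. griseus*, 2 of 4 genes were negative (3 alone), *atpB* with −1.40 (SE 0.42) and *atpE* with −1.18 (SE 0.31) in the authors' deposited table. The respiratory chain list had 5 positive members of 15 (adjusted p = 0.92; 5 alone), with *sdhC* at 0.95 (SE 0.33) in the authors' deposited table, and its median was −0.08. The *sdhC* call was lost when scaled without the 10 most abundant genes (0.79, adjusted p = 0.102). Hopanoid genes had 2 positive members of 5 (adjusted p = 0.0536; 2 alone), *shc*, the squalene-hopene cyclase, with 1.93 (SE 0.25) and *hpnH* with 1.63 (SE 0.35) in the authors' deposited table. The list's adjusted p was 0.00627 against all genes and 0.0481 when scaled without the 10 most abundant genes, but 0.191 with ranks and 0.553 when centred on tag spans. In the oxidative stress list 2 of 12 were positive (adjusted p = 0.469; 2 alone), and *katG* had 1.12 (SE 0.23) in the authors' deposited table. The other, *soxR*, had a fitted fold beyond 15 and is given no size.

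Translation factors had 2 positive members and 1 negative of 11 (adjusted p = 0.612; 4 alone), with *tsf* at 1.27 (SE 0.29) and a *tuf* row at −0.98 (SE 0.34) in the authors' deposited table. That call of *S. griseus tuf* (SGR_RS31180) was lost when centred on the median of all genes (−0.855, adjusted p = 0.0703) or of the tag span (−0.809, adjusted p = 0.0947). Another *tuf* row, SGR_RS14045, had 0.37 (SE 0.26) in the authors' deposited table and did not pass. The ribosomally made peptides had 1 positive member, *fxsT* with 0.92 (SE 0.24) in the authors' deposited table, and 1 negative of 6 (adjusted p = 0.571; 2 alone). That negative member, *lanM*, had a fitted fold beyond the limit below which a size is given here. Of 5 sigma factor genes 1 passed (adjusted p = 0.883; 1 alone), *sigE* with 1.31 (SE 0.26) in the authors' deposited table. Of 6 *rrf* rows, which encode 5S ribosomal RNA, 1 passed (adjusted p = 0.0536; 1 alone), with −1.16 (SE 0.25) in the authors' deposited table. That list passed with ranks (adjusted p = 0.0202) and when scaled without the 10 most abundant genes (adjusted p = 0.0462). None of the 4 development, 4 siderophore, 3 ectoine or 4 acyl-CoA precursor genes passed, and 0 of 2 pigment genes had an adjusted p.

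**Figure D3:**
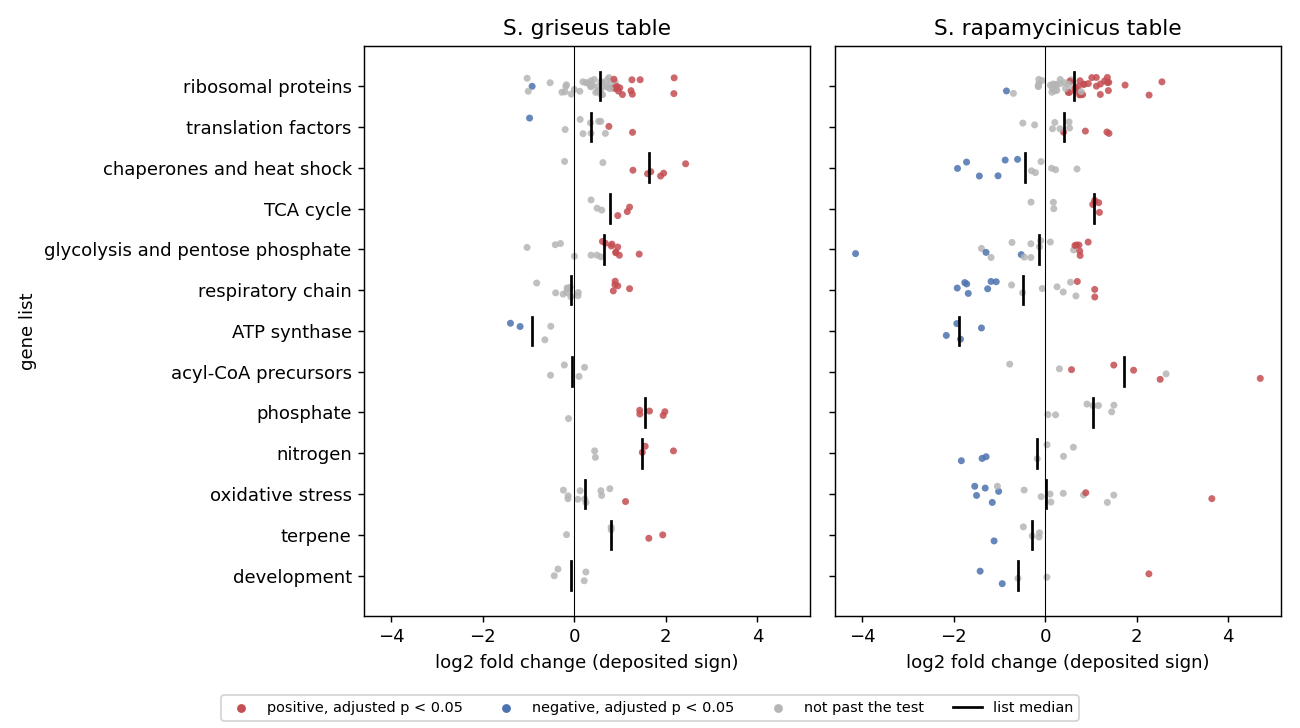
Log2 fold changes of the members of 13 gene lists in the authors' deposited tables of both species (horizontal axis), without fold changes beyond 15. Each point is a gene, coloured where its adjusted p was below 0.05, and black bars mark list medians. Chaperones had 6 of 8 members positive in *S. griseus* and 6 of 12 negative in *S. rapamycinicus*, and ATP synthase genes past the threshold were negative in both.

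The fold changes of the species were set side by side over 482 symbols found once in each table. This comparison assumes that both tables divide the groups in the same order. Across these genes, which are not independent replicates, Pearson's r was 0.09 (permutation p = 0.0486, adjusted 0.0972 over 2 relations) and Spearman's rho 0.01 (permutation p = 0.816). Positive calls in both tables were made for 27 genes, against 25.5 from independent lists (Fisher's exact test, two-sided p = 0.69), and negative calls in both for 5, against 2.7. Opposite calls were made for 15 genes positive in *S. griseus* and negative in *S. rapamycinicus*, against 10.8, and for 5 the other way, against 6.5. By the difference of fold changes over their combined SE, 146 of the 482 genes differed at an adjusted p below 0.05, 75 of them higher in *S. rapamycinicus* and 71 lower; with the sign of the *S. rapamycinicus* table turned, 69 of these 146 still differed.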

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

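The tests in this part were chosen only after the results of both tables had been seen, with the predictions on group order and scaling written before their outcome, and they assume that both tables divide the groups in the same order. They compare each symbol found once in both tables, as the log2 fold change of *S. rapamycinicus* minus that of *S. griseus* with both taken from the authors' deposited tables. Of 16 lists with at least 5 matched members, 6 differed between the species. The median difference was −1.52 for phenylacetate and aromatic degradation, −1.10 for the respiratory chain, −0.94 for the hopanoid genes of the terpene list and −0.44 for amino acid biosynthesis. It was 0.94 for DNA replication and repair and 0.66 for aminoacyl-tRNA synthetases. No fold change in this comparison was centred on tag spans, along which those of *S. rapamycinicus* shifted. Scaled to the summed counts, 5 of the 6 lists still differed, and the aminoacyl-tRNA synthetases had an adjusted p of 0.0868. With the sign of the *S. rapamycinicus* table turned, only 2 of the 6 lists differed, both in the opposite direction: phenylacetate and aromatic degradation (median difference 1.197) and amino acid biosynthesis (test on the positive side, median −0.03). The ribosomal proteins differed in addition (median difference −1.10, adjusted p = 4.81e-05).

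Of 55 named genes with a match, 32 differed between the species. The genes were named for their calls and fold changes in the same values, so this share follows in part from that choice. The differences from the authors' deposited tables were most negative for *leuA* (−6.01), *xylA* (−5.18), *hmgA* (−4.37), *treS* (−4.28), *groES* (−3.52), *eboE* (−3.40) and *cysC* (−3.19). They were −2.78 for *carB*, −2.75 for *hpnH*, −2.41 for *shc* and −2.14 for *carA* in these deposited tables. Values between −2 and −1.5 came from *nuoE* (−1.85), *nirD* (−1.84), *nuoH* (−1.78), *sigE* (−1.74), *grpE* (−1.73), *serC* (−1.70), *bldD* (−1.68), *fbaA* (−1.66) and *serA* (−1.59) in the authors' deposited tables. Smaller differences were −1.29 for *atpD*, −1.11 for *tpiA* and −0.98 for *atpE*. Positive differences from the authors' deposited tables were 6.04 for *gabT*, 2.62 for *whiG*, 2.58 for *iolB* and 2.07 for *nrdR*. The others were 1.68 for *pcrA*, 1.66 for *uraH*, 1.58 for *otsB*, 1.25 for *argS* and 1.03 for *nadA*. Scaled to the summed counts, 30 of the 32 differed, and *nadA* and *otsB* did not. The order of these values holds only for tables of the same group order. With the sign of the *S. rapamycinicus* table turned, 21 of the 32 genes differed, with *gabT* at −6.86, *leuA* at 4.30, *xylA* at 3.49 and *treS* at −3.78, and *rplJ*, at 0.37 as deposited, differed by −4.73.

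Over all matched genes, 146 of 482 differed, and a technical explanation could be that the tables divide the groups in opposite order. With the sign of one table reversed, 171 genes differed, so a reversed order would not lower their number. Which genes differ depends on the order, since 77 of the 146 no longer differed in that comparison. Scaling was the other explanation, and 129 genes differed after scaling to the summed counts. The shift along the tag order of *S. rapamycinicus*, with span medians from −0.54 to 1.11, was not removed before this comparison and also stays open. The species itself, and any difference in culture between the species, remain open and were not tested, since each species has 1 comparison.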

How the results depend on the processing

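All alternatives in this part except the filter on a mean count of at least 50 were chosen after the results were seen. The count of changed genes ranged from 562 to 705 in *S. griseus* (661 as reported) and from 2608 to 3082 in *S. rapamycinicus* (3040), with the lowest value under that filter in each. In *S. rapamycinicus* 4 gene lists passed as reported, 10 against all genes with a p-value and 7 with ranks in place of the Wald statistic. Genes with a symbol were positive more often than the rest there, and the all-gene background includes that difference. The cause of the change with ranks was not tested. Among named genes and settings, 363 results in *S. griseus* and 483 in *S. rapamycinicus* kept their side of the threshold. It was lost by 7 and 23. No named gene or called list changed sign. For lists, 210 and 260 kept it, 2 and 3 lost it and 9 and 13 gained it. The gene counts include the setting without extreme fitted folds, which left the other adjusted p-values as they were. No named gene had such a fold, so the 53 and 73 results of that setting could not change. Adjustment over every gene with a p-value was also a weak test, since 655 of 661 and 3014 of 3040 calls stayed.

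No paired analysis was possible because the tables hold no values per library, so the shared replicate numbers could not be used. For the same reason the following were planned but not run: RLE factors, library size alone from counts, a DESeq2 refit, limma voom, leaving out each library, leaving out ribosomal and transfer RNA rows, pseudocounts, camera with an estimated correlation, fry, and other gaps or flanks of clusters. Calls under other divisions of the libraries could not be counted either, and whether a single library carried a call could not be tested. A p-value was missing for 242 genes of *S. griseus* (4.79%) and 97 of *S. rapamycinicus* (0.95%).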

Other observations

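All tests of this part were chosen only after the results had been seen, among them those of the *pqq* signs and of low counts, whose values were known when they were written down; the outcomes of the tests on quartiles and on the tags around *pqq* were predicted first. Among the lists added later, amino acid biosynthesis in *S. rapamycinicus* lay below the other genes with a symbol (cameraPR adjusted p = 0.0102), which lean positive. Of its 57 genes 16 were negative, *leuA* and *cysC* among them, 6 were positive and 35 did not pass, with a median of −0.09. In the menaquinone list 3 of 8 genes were negative and 1 positive (adjusted p = 0.0102, and 0.165 with ranks). The negative members lie close together in tag order, apart from the futalosine pathway genes of the same list. Of 33 DNA replication and repair genes 18 were positive (adjusted p = 0.102, but 0.0136 with ranks and 0.00373 against all genes), with *pcrA* at 1.97 (SE 0.17) in the authors' deposited table, and of 20 aminoacyl-tRNA synthetase genes 11 were (adjusted p = 0.102, but 0.0222 with ranks and 0.00393 against all genes), with *proS* at 1.77 (SE 0.22) in the authors' deposited table. Peptidoglycan and cell division had 9 positive of 20 (adjusted p = 0.248, and 0.0305 against all genes), purine and pyrimidine synthesis 7 positive and 3 negative of 17 (adjusted p = 0.952), with *carB* at −2.19 (SE 0.21) in the authors' deposited table, and cobalamin 4 positive of 10 (adjusted p = 0.719). Heme had 3 and 3 of 10 (adjusted p = 0.838), protein export 2 and 2 of 18 (adjusted p = 0.534), type VII secretion 1 and 2 of 8 (adjusted p = 0.6), and trehalose and glycogen 2 and 1 of 9 (adjusted p = 0.92). Phenylacetate and aromatic degradation had 1 positive and 5 negative of 17 (adjusted p = 0.168, and 0.0397 with ranks), isoprenoid supply 2 and 2 of 11 (adjusted p = 0.713), and none of 16 CRISPR genes passed (adjusted p = 0.838).

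In *S. griseus*, the trehalose and glycogen list had 4 positive members of 10 (adjusted p = 0.00247, and 0.17 with ranks), the *treS* and *glg* genes among them. Amino acid biosynthesis had 6 positive of 53 (adjusted p = 0.612), with *serA* at 1.25 (SE 0.27) in the authors' deposited table, and DNA replication and repair 3 positive and 1 negative of 34. The test of that list was on the negative side (median −0.25, adjusted p = 0.0512), and it passed under 5 alternatives, among them ranks (adjusted p = 0.0171) and centring on tag spans (adjusted p = 0.0449). Protein export had 4 and 1 of 19 (adjusted p = 0.734), peptidoglycan and cell division 3 and 1 of 20 (adjusted p = 0.612) with *mraY* at 1.04 (SE 0.17) in the authors' deposited table, and aminoacyl-tRNA synthetases 1 and 2 of 17 (adjusted p = 0.469). Purine and pyrimidine synthesis had 3 positive of 17 (adjusted p = 0.469), phenylacetate and aromatic degradation 3 positive of 9 (adjusted p = 0.469), type VII secretion 1 positive of 8, *eccB* with a fitted fold beyond 15 and no size given (adjusted p = 0.776), and heme 1 negative of 7 (adjusted p = 0.469). Another *eccB* row, SGR_RS08790, had 3.81 (SE 5.16) in the authors' deposited table and did not pass. None passed among 10 cobalamin genes (adjusted p = 0.751), 6 isoprenoid supply genes (adjusted p = 0.975), 2 menaquinone genes or 2 CRISPR genes. The median fold change and the set test differed in sign in *S. griseus* for the respiratory chain (negative median) and for the ribosomally made peptide, cobalamin, aminoacyl-tRNA synthetase and heme lists (positive medians). In *S. rapamycinicus* they differed for the oxidative stress, sigma factor, heme, CRISPR and type VII secretion lists (positive medians). The mean statistic was positive but the test negative, relative to the background, for the sigma factor, amino acid, cobalamin and aminoacyl-tRNA synthetase lists of *S. griseus*. The same held for the fatty acid, sigma factor, heme and CRISPR lists of *S. rapamycinicus*.

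The arch of fold changes over the tag order of *S. rapamycinicus* was not due to low counts at the ends. Among genes with a mean count of at least 50, the sixth of 10 spans had a median 1.40 above that of the first and last spans. The lower quartile moved by 1.57 and the upper quartile by 1.48, a ratio of 0.94 (bootstrap 95% interval 0.79 to 1.13). Single genes were resampled although neighbouring statistics correlated (Spearman's rho 0.536), so this interval is probably too narrow. Such a ratio could follow from a shift of every gene by a similar amount, as a difference in gene dosage between the groups would give. That was not tested, and DNA coverage along the chromosome would decide it. A cause that changes transcription over the same region could give the same values, and no DNA measurement or coordinates were used here. In *S. griseus* the medians of the 10 spans had a range of 0.52, within the shuffled blocks (highest 1.08, permutation p = 0.07).

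The *pqq* genes alone do not settle whether the numerator of the *S. rapamycinicus* table is the group with the PQQ operon. That 5 of 5 were positive raised the question, so it is no independent test of it. If the group labelled with the operon had the higher *pqq* level, these signs would make it the numerator. That level is known here only from the same values of the *pqq* genes. A positive stretch of tags wider than their own run did not account for their sign. That run held 7 positive tags, 5 of them with a *pqq* symbol. Of the 40 tags around the run 0 were called positive, against 16.2% of all rows. The count began where the run ended, so it left out the run's positive tags without a *pqq* symbol. The direction stays open, because no label gives the numerator and the lower group also had *pqqA* transcripts by the estimated means.

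In *S. griseus*, 94 rows had a fitted log2 fold change beyond 15 in the authors' deposited table, of which 59 had no p-value (62.8%, against 3.7% of other rows) and 35 were called. Low counts did not set them apart, since 16% of them and 14.7% of other rows had a mean count below 10. In *S. rapamycinicus* 8 rows had such a fitted fold, 6 of them called. There 25% of these rows and 16.6% of other rows had a mean count below 10. Rows without a p-value were more frequent in *S. griseus* (Fisher's exact test, two-sided, odds ratio 5.22, p = 8.74e-48). The rows of a species share the same libraries and are not independent, so this p-value does not measure a difference between the species beyond these libraries. The transfer-messenger RNA gene *ssrA* alone held 8.54% of the summed mean counts in the authors' deposited table of *S. griseus* and 1.83% in that of *S. rapamycinicus*, where it was negative at −0.69 (SE 0.27, adjusted p = 0.0357). Outlying counts in single libraries stay open as a cause for these rows, since the missing p-values go with them and no values per library were used here. These weighings of extreme folds and of low counts in the long runs of *S. rapamycinicus* were dropped from the formal comparison after their results had been seen. For the runs, the SE was predicted to be higher in long runs if low counts made them; it was, but narrowly (0.378 against 0.353), and the permutation test (p = 0.14) was added only after those medians were known. A mean count below 50 was less frequent in the runs, at 13% against 20.1% of the other changed genes, which goes against low counts as their cause.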
